A study of Mus musculus with 8 samples.

How the data were processed

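Foxp3 binding was profiled by CUT&Tag, in which an antibody tethers a protein A/G-Tn5 transposase to chromatin so that DNA near the antibody target is cut and tagged for sequencing. Regulatory T (Treg) cells came from mice heterozygous for an hCD2-tagged Foxp3 allele, either wild-type (WT) or R397W, and a GFP-tagged Foxp3 allele. The sort kept CD4+ cells positive for hCD2 and negative for GFP, so the profiled cells expressed the hCD2-tagged allele. Per the labels' protocols, cells were fixed in 0.1% formaldehyde for 2 minutes, spike-in nuclei were added, 0.5 µg of a rabbit polyclonal anti-Foxp3 or of normal rabbit IgG was used, and libraries were amplified for 14 to 15 PCR cycles. There were 4 groups of 2 libraries each, namely Foxp3 and IgG libraries of WT and of R397W cells, grouped by their titles. The labels do not say whether the libraries numbered 1 and 2 came from separate mice. P-values that compare libraries therefore measure only the spread between these samples, which may be technical. Fisher's exact tests of site classes use no library values and describe sites or genes. Camera compares a set of sites with the other sites.

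The deposited files hold a normalised signal per library at Foxp3 binding sites that the authors sorted into 3 classes, named common, cTreg-specific and eTreg-specific (eTreg, effector Treg). How the sites were called is not given in the sources used here. The submitters' processing notes name Bowtie2 2.5.2, DiffBind 3.12.0 and the builds mm10 and dm6, with no roles, and coordinates are taken here as mm10. Most sites span 400 bp. The file names describe the signal as spike-in normalised, per the authors. Within a library and file, 100% of values above 0 were whole multiples of the smallest one (tolerance 0.01), so whole reads could be recovered. The factor of each library equalled the median-of-ratios size factor of that file's own sites to within 6.87e-08 percent, computed from the sites with reads in all 8 libraries (815 common, 58 cTreg-specific and 65 eTreg-specific sites). The 3 files were therefore scaled separately, and the ratio of a pair of libraries' factors differed between files by up to 2.09-fold. A genome-wide gain or loss of signal in a library is removed by such factors. Whether reads were thinned to a spike-in scale before counting is not given in the sources used here.

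Reads in the listed sites ranged from 111274 to 394196 per library. These are sums over the listed sites, not library depths, and duplicate removal is not given in the sources used here, so counting intervals cover counting error only. Bootstrap errors come from 1000 draws of sites and describe site sampling, not the spread between mice.

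The main test was limma 3.58.1 in R 4.3.3 (trended empirical Bayes, two-sided) on log2(normalised read count + 1) of the 4 Foxp3 libraries, R397W minus WT, with Benjamini-Hochberg adjustment over all 5521 sites and a threshold of 0.05. Fold changes are on that scale, which understates the change of weak sites. No site was filtered out. A fit over all 8 libraries, with a mean per group, compared Foxp3 with IgG. Site classes were compared by the median log2 value of each class per library, with exact permutation tests, which for 2 against 2 cannot give a p below 0.33, and with fry and camera from limma (preset correlation 0.01, and again with an estimated one). That median sat at 0 in 1 R397W library, and the 3 files had separate factors. The ratio of recovered reads of one class to another within a library, in which every library factor cancels, was therefore added after the data were examined. The class makeup of the gene lists was compared by Fisher's exact test, also added then. Whole reads were tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, with the deposited factors as offsets. The other alternatives were pseudocounts of 0.5 and 5, removal of the lowest 25% of sites, other scalings, a replicate block, no trend, IgG subtraction, a 10 kb limit for genes, and each library left out in turn.

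Each site received the protein-coding gene (RefSeq, GRCm38.p6) whose body, widened by 5 kb, held its centre, otherwise the nearest gene end within 100 kb. The plan was to use transcription start sites, but the gene table used here has no strand. Distances are therefore to the nearer gene end, and exons, introns and UTRs were not analysed here. A gene was found for 5210 sites, 3505 of them inside a gene body. Motif analysis was not run because no genome sequence was used here. The 11 gene lists were fixed before the data were examined, namely core Treg, effector Treg, naive and resting T cell, AP-1, IRF and NFAT factors, conventional T cell cytokines, T cell receptor signalling, NF-kB and TNF receptor, B cell, myeloid cell, CD8 T and NK cell, and housekeeping.

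Named sites followed a rule that was likewise fixed then. It takes the called sites of each class or, where none is called, the 2 sites with the largest absolute fold change among those whose libraries do not overlap and whose mean is above the class median. It adds the site with the highest WT mean at the 3 strongest genes of each of the core Treg, effector Treg, naive and AP-1 lists, and at Foxp3, Il2ra, Ctla4, Ikzf2, Icos, Batf, Prdm1, Tcf7, Lef1 and Bach2. The site with the highest WT mean of each class completes it. This gave 25 sites, and none was assigned to Batf or Prdm1.

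The tests were tested on simulated data for the comparison of R397W with WT, with 200 of 5521 sites changed 4-fold or 8-fold up or down. The changed sites were drawn only from those whose mean over the Foxp3 libraries was above the median, so recovery at weaker sites was not measured. At a dispersion of 0.02, limma recovered 59.5% of the changed sites over these fold sizes together, edgeR 100% and DESeq2 95.5%. With 1 common dispersion for all sites, estimated from the Foxp3 libraries at 3.31, limma and edgeR recovered 0%. DESeq2 recovered 5% while calling 130 unchanged sites. A spread that differs between sites was not simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.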

Results

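Foxp3 occupancy was measured by CUT&Tag in Treg cells, CD4+ T cells that restrain immune responses and depend on the transcription factor Foxp3. The cells were freshly sorted from lymph nodes and spleen of C57BL6/J mice and expressed either WT Foxp3 or the R397W form, a missense change in the forkhead domain that contacts DNA. Each genotype had 2 Foxp3 libraries and 2 IgG libraries, the latter as background. Signal was given at 3847 common, 727 cTreg-specific and 947 eTreg-specific Foxp3 binding sites. Reads in these sites numbered 279737 and 394196 in the WT Foxp3 libraries (replicates 1 and 2), 111274 and 281252 in R397W Foxp3, 297706 and 288223 in WT IgG, and 111359 and 258781 in R397W IgG. Coverage was uneven. In WT Foxp3 replicate 1, 3.13% of the 5521 sites had no reads, against 44.4% in replicate 2. The corresponding shares were 15.7% and 55.5% in R397W Foxp3, 27.0% and 66.8% in WT IgG, and 18.9% and 60.1% in R397W IgG.

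The eTreg-specific and cTreg-specific classes were tested in the 7 gene lists with 3 or more sites, and effector and naive lists stood out. Sites of effector Treg genes, a list of receptors, cytokines and transcription factors of activated Treg cells, were eTreg-specific in 27 of 53 cases (50.9%), against 16.5% of the other 5157 sites with a gene (Fisher's exact test, two-sided, adjusted p = 6.93e-08 over 14 tests). Sites of naive and resting T cell genes, such as the lymph node homing receptor gene Ccr7 and the transcription factor genes Tcf7, Lef1 and Satb1, were cTreg-specific in 41 of 70 cases (58.6%), against 12.1% of the others (Fisher's exact test, adjusted p = 1.03e-18). Each list was scarce in the opposite class. Only 1 of 53 effector Treg sites was cTreg-specific and 4 of 70 naive sites were eTreg-specific (adjusted p = 0.0402 for each by Fisher's exact test). Core Treg sites had a makeup close to that of the other sites, with 28 common, 3 cTreg-specific and 8 eTreg-specific.

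Sites of one gene are not independent, so genes were also counted once, by whether they had any site of a class. A gene with more sites is more likely to have one, and this was not adjusted for. The 18 effector Treg genes had 53 sites and the other 2742 genes 5157. The 15 naive genes had 70 sites and the other 2745 genes 5140. An eTreg-specific site was present at 13 of 18 effector Treg genes with a site (72.2%) and at 23.3% of other genes (Fisher's exact test, adjusted p = 0.000116). A cTreg-specific site was present at 11 of 15 naive genes (73.3%) and at 17.0% of others (adjusted p = 3.79e-05). The scarcity in the opposite class did not pass at the level of genes (adjusted p = 0.686 for effector and 0.802 for naive genes, Fisher's exact test). The NF-kB and TNF receptor list had 5 of 11 sites in the eTreg-specific class, which did not pass (adjusted p = 0.0707).

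**Figure D1:**
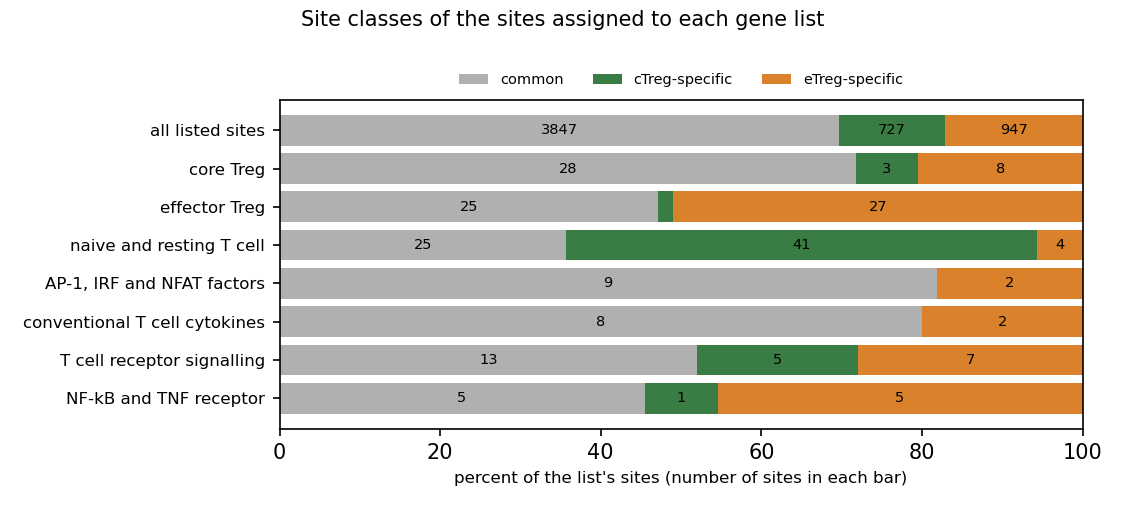
Percent of sites in the common, cTreg-specific and eTreg-specific classes for all listed sites and for the sites assigned to each gene list, with the number of sites written in the bars. Effector Treg genes have 27 of 53 sites in the eTreg-specific class and naive and resting T cell genes have 41 of 70 in the cTreg-specific class.

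The comparison of Foxp3 with IgG asks how far the signal stood above background. In WT cells the mean normalised read count per site was higher with anti-Foxp3 than with IgG in every class and both replicates, by 1.56-fold and 1.21-fold at common sites, 1.26-fold and 1.18-fold at cTreg-specific sites, and 1.70-fold and 1.44-fold at eTreg-specific sites (replicates 1 and 2). In R397W cells the ratios were 1.12 and 1.06 at common sites, 0.896 and 1.42 at cTreg-specific sites, and 0.880 and 1.03 at eTreg-specific sites. The mean ratio at eTreg-specific sites was 1.57 ± 0.189 (SD, n = 2) in WT and 0.954 ± 0.104 (SD, n = 2) in R397W, and at common sites 1.39 ± 0.251 and 1.09 ± 0.0451. Both WT ratios exceeded both R397W ratios in these classes, which gave p = 0.33 in an exact permutation test, two-sided, the smallest p that 2 against 2 allows. At cTreg-specific sites the ratios overlapped (exact permutation p = 1). The deposited factors remove a difference shared by most of a file's sites, so these ratios are relative to the sites used for the factors.

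On the planned scale, the median log2 value per library, Foxp3 minus IgG was 2.09 at common, 0.69 at cTreg-specific and 1.44 at eTreg-specific sites in WT, and 0.10, −0.13 and −0.02 in R397W. These medians are set by the floor, since the class medians of both IgG libraries numbered 2 and of R397W Foxp3 replicate 2 were 0. The mean log2 difference at common sites was 1.47 and 0.98 in WT (replicates 1 and 2) and 0.21 and 0.16 in R397W. It was 1.19 and 0.98 against −0.06 and 0.47 at cTreg-specific sites, and 1.66 and 1.23 against 0.13 and 0.32 at eTreg-specific sites. These means also depend on sites without reads. In WT, 3.67% and 43.0% of common sites lacked reads with anti-Foxp3 and 26.2% and 62.9% with IgG (replicates 1 and 2). In R397W the shares were 15.3% and 52.8% with anti-Foxp3 and 17.6% and 55.9% with IgG. Coverage and occupancy are therefore not separated by the means. By limma over the 8 libraries, 4 sites stood above IgG in WT and 0 in R397W. At unadjusted p under 0.05, 133 sites were above and 9 below IgG in WT, and 50 above and 31 below in R397W. The test of the difference between genotypes in Foxp3 over IgG gave 0 sites, with 15 higher and 76 lower in R397W at unadjusted p under 0.05.

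The 4 sites, named after their values were seen, are common sites 17823 bp from Ramp3, 2948 bp from Pnrc2 (chromosome 4, 135876594 to 135876994), 61664 bp from Glrp1 (chromosome 1, 88587373 to 88587773) and inside Arhgef10 (chromosome 8, 14985763 to 14986163). Adjusted p-values were 0.000754 at Ramp3, 0.00188 at Pnrc2, 0.00188 at Arhgef10 and 0.0494 at Glrp1. In WT IgG replicate 2 the value was 0.498 at Pnrc2, 0.498 at Glrp1 and 0 at Arhgef10, while in WT IgG replicate 1 it was 324, 234 and 239.9. In replicate 1, WT Foxp3 lay below IgG at Pnrc2 (293 against 324) and little above it at Ramp3 (849 against 831), and the fit did not pair the antibodies of a cell sample. The count of 4 fell to 0 without WT IgG replicate 2, without any one of the R397W libraries, or with a pseudocount of 5. It was 29 without WT IgG replicate 1, and 34 and 188 without WT Foxp3 replicates 1 and 2.

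**Figure D2:**
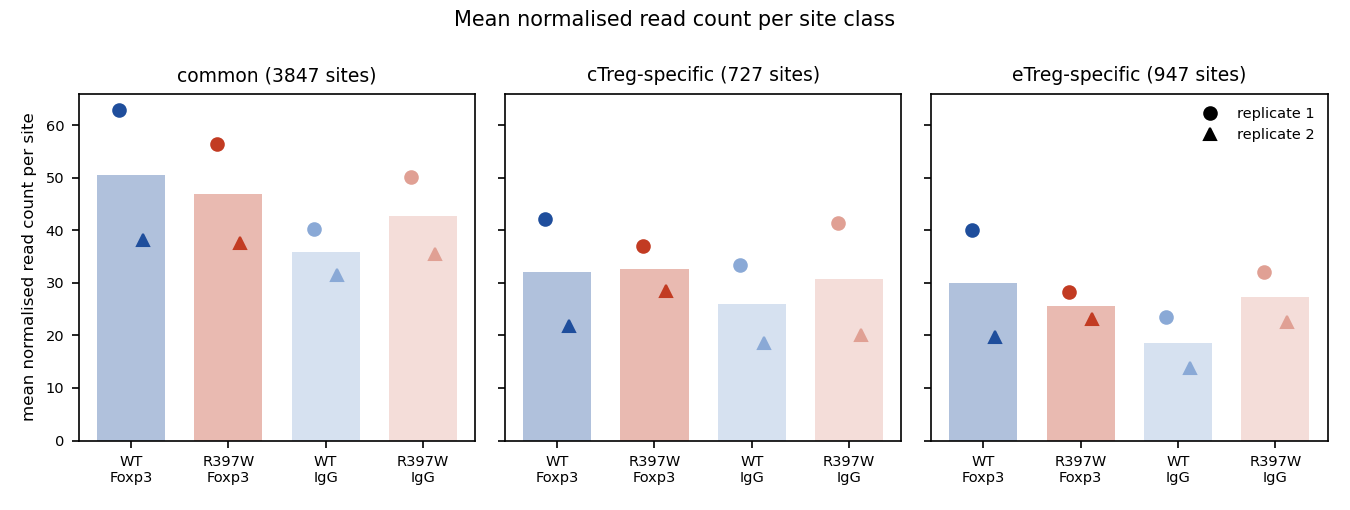
Mean normalised read count per site (vertical axis) in each site class for the 4 groups, with points for the libraries and bars for the mean of 2 libraries. WT Foxp3 lies above WT IgG in every class within each replicate number, and the classes carry separate library factors, so heights are compared within a panel.

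R397W was compared with WT in the Foxp3 libraries to ask which sites differ in occupancy when Foxp3 carries the change. Of the 5521 sites, 3334 had a lower fitted value in R397W on the deposited scale, and 3191 did with reads scaled to equal totals. With each library centred on its common-site median 1496 did, but that median was 0 in R397W Foxp3 replicate 2. No site passed in limma (lowest adjusted p = 1). At unadjusted p under 0.05 there were 18 sites, 15 of them lower in R397W. The balance depended on the scaling, with 13 lower and 5 higher at equal totals. Centring on the common-site median gave 12 lower and 208 higher. The edgeR test on recovered reads called 0 sites (40 at unadjusted p under 0.05, 28 lower and 12 higher; lowest adjusted p = 0.0752), and DESeq2 called 6 (117 at unadjusted p under 0.05, 76 lower and 41 higher). The R397W and WT libraries did not overlap at 1051 sites, 696 of them lower in R397W and 355 higher. Chance alone would separate the genotypes at 33.3% of sites if no values were tied. The count lies below that share of the 5521 sites, so by itself it is not evidence of a difference between genotypes.

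The mean normalised read count at common sites was 50.5 ± 17.5 in WT and 46.9 ± 13.3 in R397W (SD, n = 2). It was 32.1 ± 14.4 and 32.7 ± 6.07 at cTreg-specific sites, and 29.9 ± 14.3 and 25.6 ± 3.62 at eTreg-specific sites. The R397W to WT ratio at eTreg-specific sites was 0.705 between the replicates numbered 1 and 1.17 between those numbered 2. None of the class means differed by more than the spread between replicates (exact permutation p = 0.667 at common sites and 1 at both others). The fry test gave adjusted p = 0.882 for each class. Simulated changes of 4-fold and 8-fold, placed at sites above the median signal, were not recovered by limma with the common dispersion of 3.31 at every site. A spread that differs between sites was not simulated, so this does not cover sites with less spread. Leaving out WT Foxp3 replicate 2 gave 643 calls, each lower in R397W and each at a site with value 0 in both R397W libraries, where the R397W replicates have no spread.

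The sites with the largest fold changes among those without overlap are given as values, since limma called none of them and DESeq2 only the one near Dusp1 (adjusted p = 0.00933). At a common site inside Fndc3b (chromosome 3, 27458382 to 27458782) the value was 65.9 ± 2.29 in WT and 0 in both R397W libraries (SD, n = 2). Near Pttg1, the securin gene, a common site 34652 bp from the gene (chromosome 11, 43385392 to 43385792) had 98.5 ± 17.5 in WT and 1.31 ± 1.86 in R397W. Among eTreg-specific sites, one lay 24331 bp from Dusp1, which encodes a MAP kinase phosphatase (chromosome 17, 26532603 to 26533003), and had 110.4 ± 7.87 in WT and 0 in both R397W libraries. Another, inside Tbc1d4 (chromosome 14, 101480537 to 101480937), had 63.1 ± 14.9 in WT and 0 in both R397W libraries. The cTreg-specific pair went in opposite directions. A site 70124 bp from Phlda1 (chromosome 10, 111578573 to 111578973) had 53.2 ± 18.1 in WT and 0 in R397W, and a site inside Ssh2 (chromosome 11, 77371170 to 77371570) had 0 in WT and 46.6 ± 6.31 in R397W. IgG was high at some of these sites, with 249 near Pttg1 in R397W IgG replicate 2 and 128 near Phlda1 in R397W IgG replicate 1. Inside Ssh2, R397W IgG was 58.4 and 42.4 (replicates 1 and 2), close to R397W Foxp3 at 42.1 and 51.1. In WT IgG replicate 1 the value was 91.2 near Pttg1 and 52.2 inside Fndc3b. WT Foxp3 replicate 1 had 86.1 and 64.3 at these 2 sites.

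The site with the highest WT mean of each class is also given as values. At the common site 17823 bp from Ramp3 (chromosome 11, 6695101 to 6695501) the value was 971 ± 172 in WT and 861 ± 66.4 in R397W, with IgG at 831 and 269 in WT and 686 and 639.6 in R397W. The eTreg-specific site inside Alpk2 (chromosome 18, 65381626 to 65382026) had 343 ± 126 in WT and 178 ± 74.6 in R397W, a log2 fold change of −0.95 (SE 0.55). The strongest cTreg-specific site was 16469 bp from Tcf7, which encodes the transcription factor TCF1 of naive T cells (chromosome 11, 52299652 to 52300052), with 293 ± 190.3 in WT and 151 ± 129 in R397W. IgG near Tcf7 was 376 and 124 in WT and 387 and 267 in R397W (replicates 1 and 2). It exceeded Foxp3 in every same-numbered pair except WT replicate 2.

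Whether the effector sites were affected more than the others was examined as the ratio of recovered reads in one class to those in another within each library, so that no scale factor enters. The log2 ratio of reads at eTreg-specific to cTreg-specific sites was 0.26 and 0.66 in WT Foxp3 (replicates 1 and 2) and −0.32 and −0.06 in R397W Foxp3. Its mean was 0.46 ± 0.28 in WT and −0.19 ± 0.19 in R397W (SD, n = 2), a difference of −0.65 (bootstrap SE over sites 0.08), with −0.59 and −0.72 for the replicates numbered 1 and 2. The same log2 ratio in IgG was 0.32 and 0.20 in WT and −0.18 and 0.00 in R397W, a difference of −0.35 (bootstrap SE 0.11). All 4 WT libraries lay above all 4 R397W libraries. With the antibodies averaged per cell sample, the exact permutation p was 0.33, the smallest that 2 against 2 allows.

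Reads at eTreg-specific sites were also set against those at common sites. The log2 difference was −0.41 (bootstrap SE 0.07) in Foxp3 libraries, −0.51 and −0.31 for replicates 1 and 2, and 0.01 (bootstrap SE 0.09) in IgG libraries. The Foxp3 minus IgG value was 0.54 and 0.65 in WT and 0.11 and 0.26 in R397W, a difference of −0.41 (bootstrap SE 0.11, pooled SD 0.10). For the Foxp3 libraries alone the exact permutation p was 0.33, although WT replicate 2 (−2.69) and R397W replicate 1 (−2.70) nearly touched. It was 0.667 with each class capped at its 99th percentile, for the share of sites with reads, and for the mean of both antibodies. For cTreg-specific relative to common sites the log2 difference was 0.24 (bootstrap SE 0.06) in Foxp3 and 0.35 (bootstrap SE 0.09) in IgG libraries, and both lay within the pooled SD of the replicates, 0.53 and 0.41.

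The planned median statistic gave other values. R397W Foxp3 replicate 2 had no reads at most sites of each class, so its medians were 0. The R397W minus WT difference in median log2 value was −1.69 at common, −0.43 at cTreg-specific and −1.21 at eTreg-specific sites (exact permutation p = 0.667 for each). Without R397W Foxp3 replicate 2 these were 0.87, 1.93 and 0.87, and without WT Foxp3 replicate 1 they were −0.51, 1.76 and 0.35. Without WT Foxp3 replicate 2 they were −2.87, −2.61 and −2.77, and without R397W Foxp3 replicate 1 they were −4.26, −2.78 and −3.28. The difference between classes was 0.48 for eTreg-specific minus common, 1.27 for cTreg-specific minus common, and −0.78 for eTreg-specific minus cTreg-specific (exact permutation p = 0.667, 0.33 and 0.667). The first was −0.01 without R397W Foxp3 replicate 2, 0.11 without WT Foxp3 replicate 2 and 0.98 without R397W Foxp3 replicate 1. The second was 0.26 without WT Foxp3 replicate 2 and 2.27 without WT Foxp3 replicate 1, and the third −0.16 and −1.41. Camera, on reads scaled to equal totals, placed eTreg-specific sites below the other sites in R397W (adjusted p = 0.00475 with the preset correlation), and this call was lost with adjusted p = 0.813 with an estimated correlation.

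**Figure D3:**
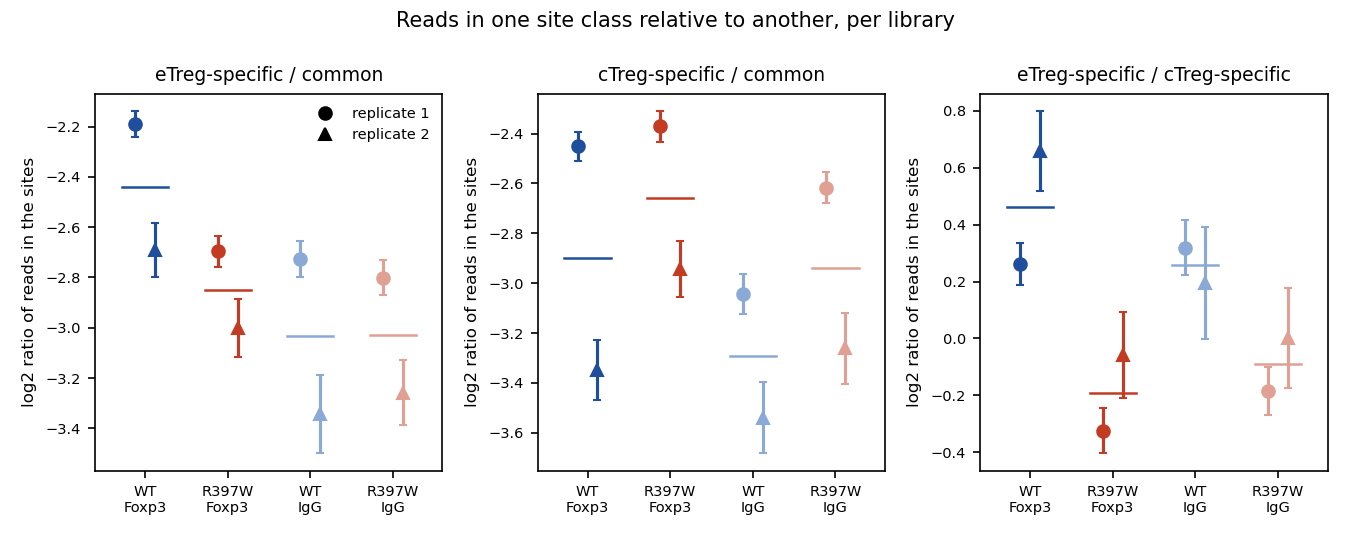
Log2 ratio of recovered reads between site classes (vertical axes) for each library of the 4 groups, with bootstrap standard errors over sites and a line at the mean of each group. In the panel of eTreg-specific over cTreg-specific sites, the WT libraries lie at 0.20 to 0.66 and the R397W libraries at −0.32 to 0.00, in Foxp3 and in IgG.

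The gene lists were compared between genotypes to ask whether Treg programmes differed in Foxp3 signal. The median log2 fold change, R397W minus WT, was −0.85 over 39 core Treg sites, −1.05 over 53 effector Treg sites and −0.71 over 70 naive and resting T cell sites, and it became 0.84, 0.64 and 0.98 when each library was centred on its common-site median. Without R397W Foxp3 replicate 2 these medians turned to 0.43, 0.75 and 0.46, and without WT Foxp3 replicate 1 they were 0, 0.60 and 0.82. Without R397W Foxp3 replicate 1 they stayed negative, at −2.10, −2.64 and −2.10, as they did without WT Foxp3 replicate 2, at −2.24, −2.53 and −1.92. With all libraries it was −0.28 over 11 sites of AP-1, IRF and NFAT factors, −0.57 over 25 T cell receptor signalling sites, −1.32 over 10 cytokine sites and −1.58 over 11 NF-kB and TNF receptor sites. Without R397W Foxp3 replicate 2 these 4 medians were 0.77, −0.15, 0.20 and −0.13, and without WT Foxp3 replicate 1 they were −0.45, 0.07, −0.22 and 0.16. Without WT Foxp3 replicate 2 they were −1.59, −1.34, −1.94 and −3.21, and without R397W Foxp3 replicate 1 they were −0.50, −1.70, −2.31 and −1.50. The median over all sites was −0.39. No site of any list passed, adjusted over all sites or adjusted over the list alone, no listed site had an unadjusted p under 0.05, and no list passed in fry (adjusted p = 0.807 for each) or camera (lowest adjusted p = 0.609, for NF-kB and TNF receptor genes, and 0.921 with an estimated correlation). With groups listed at 0 set to a floor of 3 reads per library, the medians were −0.70 for core Treg, −0.62 for effector Treg, −0.47 for naive genes and −0.12 over all sites. That centring moved the median over all sites from −0.39 to 1.31 and made the medians of these 7 lists positive. It rests on a common-site median of 0 in R397W Foxp3 replicate 2. Scaling to equal totals gave −0.31 over all sites and kept the list medians negative.

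Among core Treg genes, Il2ra had the site with the highest WT mean. Inside Il2ra, which encodes the high-affinity chain of the interleukin-2 receptor (chromosome 2, 11653356 to 11653756), the value was 448 ± 169 in WT and 239 ± 15.3 in R397W (SD, n = 2), a log2 fold change of −0.85 (SE 0.45), with IgG at 138 and 70.7 in WT and 256 and 159.7 in R397W. The strongest site inside Foxp3 itself (chromosome X, 7583928 to 7584328) had 223 ± 14.9 in WT and 125 ± 69.6 in R397W, and IgG of 194 and 29.9 in WT and 303 and 0 in R397W. A site 4227 bp from Izumo1r, the folate receptor 4 gene (chromosome 9, 14907978 to 14908378), had 127 ± 108 in WT and 240.2 ± 106 in R397W. At Ctla4, an inhibitory receptor gene (chromosome 1, 60913269 to 60913669, eTreg-specific, inside the gene), the values were 97.0 ± 137 and 95.7 ± 30.5. At Ikzf2, which encodes Helios (chromosome 1, 69691927 to 69692327, 4776 bp from the gene), they were 53.8 ± 32.0 and 9.19 ± 13.0.

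For the effector Treg list, the eTreg-specific site inside the inhibitory receptor gene Tigit (chromosome 16, 43664097 to 43664497) had 204 ± 141 in WT and 80.4 ± 55.2 in R397W, while IgG was 11.9 and 0 in WT and 49.6 and 0 in R397W. The common site inside Tnfrsf9, the 4-1BB gene (chromosome 4, 150924320 to 150924720), had 128 ± 20.3 and 66.9 ± 94.7. Inside Cd44, an adhesion receptor gene of activated T cells (chromosome 2, 102873909 to 102874309), the values were 108 ± 125 and 109.9 ± 145. Inside Icos, a costimulatory receptor gene (chromosome 1, 60977662 to 60978062), they were 33.4 ± 42.0 and 30.7 ± 27.1. Among AP-1 and IRF genes, the site 811 bp from Fosl2 (chromosome 5, 32135461 to 32135861) had 277 ± 44.2 in WT and 229 ± 47.6 in R397W. A site 26587 bp from Fos (chromosome 12, 85447103 to 85447503) had 185 ± 233 and 167 ± 128. The site inside Irf4, whose product binds DNA together with BATF (chromosome 13, 30760246 to 30760646), had 74.7 ± 18.2 and 26.3 ± 37.1.

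Naive and resting genes included the site 11556 bp from Ccr7 (chromosome 11, 99132443 to 99132843), with 163 ± 9.43 in WT and 72.9 ± 40.0 in R397W, a log2 fold change of −1.26 (SE 0.73). The cTreg-specific site inside Satb1, a chromatin organiser gene (chromosome 17, 51833024 to 51833424), had 179 ± 103 and 119.8 ± 76.1, with IgG of 366 in WT IgG replicate 1. A site 52901 bp from Lef1 (chromosome 3, 131057196 to 131057596) had 113 ± 92.2 and 79.3 ± 49.1. The site inside Bach2, a repressor of effector genes (chromosome 4, 32238503 to 32238903), had 145 ± 96.8 and 174 ± 67.6. None of the 25 named sites passed in limma (adjusted p = 1 for each).

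**Figure D4:**
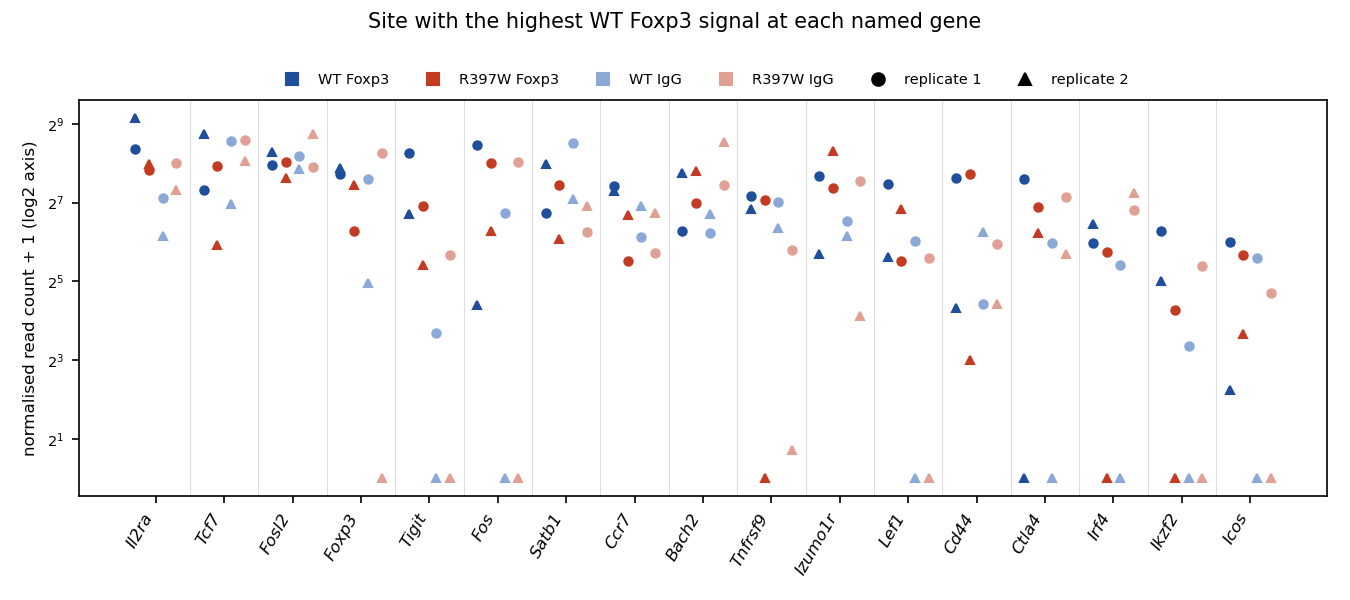
Normalised read count plus 1 (log2 axis) at the strongest WT site of each named gene, in Foxp3 and IgG libraries of both genotypes, with circles for replicate 1 and triangles for replicate 2. Points at the bottom are values of 0, as for R397W Foxp3 replicate 2 at Ikzf2, Irf4 and Tnfrsf9, and IgG lies within the range of Foxp3 at many genes.

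The lists of other cell types and of housekeeping genes, of 8 genes each, had few sites. How many sites such short lists would hold by chance was not tested. The sites are the authors' fixed list of Foxp3 binding sites, so the counts do not measure the purity of the cells. The B cell and myeloid lists had 0 sites each. The CD8 T and NK cell list had 2 sites, with mean values of 73.4 and 6.53 in the WT Foxp3 libraries and 11.5 and 7.03 in R397W. The housekeeping list also had 2 sites, with mean values of 69.1 and 65.9 in WT and 86.6 and 139 in R397W.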

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

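The test of each site's difference in Foxp3 over IgG between genotypes was chosen after the values were seen. At 3 of the 25 named sites, anti-Foxp3 exceeded IgG in both WT pairs and lay below it in both R397W pairs of libraries with the same number, and 0 sites showed the opposite. These sites were named for their WT Foxp3 signal or their difference between genotypes, so the count says nothing about how common the pattern is. Inside Irf4, the WT pairs were 61.9 against 41.6 and 87.5 against 0, and the R397W pairs 52.5 against 111 and 0 against 150.2, a difference between genotypes in log2 Foxp3 over IgG of −7.67, whose size depends on the pseudocount because a pair in each genotype contains a 0. Near Ccr7 the difference was −0.97, and inside Bach2, where the second R397W pair was 222 against 374, it was −1.14. In limma none of these differences passed (adjusted p = 1.00 for each). Over the 11 sites of the NF-kB and TNF receptor list, mean values were 65.2 against 47.7 and 39.7 against 16.1 in WT, and 44.5 against 68.5 and 19.3 against 41.9 in R397W. The difference in log2 ratio was −1.74 (pooled SD 0.49), from −2.17 to −1.32 with the Foxp3 and IgG libraries of one cell sample left out in turn, and this list difference was not tested. It was negative in the other 6 lists too, with −0.97 (pooled SD 0.77) for core Treg, −0.65 (0.08) for effector Treg, −0.58 (0.25) for naive and resting T cell, −1.18 (0.57) for AP-1, IRF and NFAT, −0.22 (1.02) for cytokine and −0.29 (0.05) for T cell receptor signalling sites. The core Treg value was −0.20 without R397W replicate 1, and the cytokine value turned to 0.80 without WT replicate 1, while the other 4 stayed negative with any cell sample left out. The site classes also had lower mean Foxp3 to IgG ratios in R397W. These were 1.39 in WT and 1.09 in R397W at common sites, 1.22 and 1.16 at cTreg-specific sites, and 1.57 and 0.954 at eTreg-specific sites. A negative value is therefore not particular to these lists.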

How the results depend on the processing

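The mean in place of the median, the ratio of recovered reads, the separate fits per file and the leaving out of a cell sample from Foxp3 over IgG were chosen after seeing the data. The count of called sites stayed at 0 under both other pseudocounts, the filter, both other scalings, no trend, IgG subtraction, separate fits per file and edgeR. With the replicate block it was 0, with 140 sites at unadjusted p under 0.05 against 18 without it. The number itself marked a shared difference, as 465 sites were lower and 12 higher in the libraries numbered 2 over all 8 libraries. Deviations of same-numbered libraries correlated at 0.17 between WT and R397W, and with only 2 numbers whose meaning the labels do not give, the genotypes were taken to share only a number. DESeq2 called 6 sites, 3 common and 3 eTreg-specific. It left 64 adjusted p-values NA, which is the number of sites listed at 0 in all 4 Foxp3 libraries. In data simulated with 1 common dispersion it called 141 sites, 130 of them unchanged. Only 6 were called here, so that simulation cannot judge these calls. Why DESeq2 called more sites than limma was not tested. Leaving out each Foxp3 library gave 0 to 643 calls (0 to 446 common, 0 to 60 cTreg-specific, 0 to 137 eTreg-specific), and each of the 643 rested on a pair of R397W libraries at 0. A lone library was assumed to vary like the others. WT sites above IgG numbered 0 to 188 with libraries left out and 0 with a pseudocount of 5; the cause was not tested. The R397W minus WT difference in class medians kept its negative sign in 25 of 33 alternatives, and at common sites ranged from −4.26 to 0.87 with libraries left out. The replicate block is balanced, so it cannot change any median or fold change and its unchanged values are no support. For eTreg-specific minus common, the difference of 0.48 became −1.81 with the lowest 25% of sites left out, −0.31 with means and −0.41 with read ratios; for cTreg-specific minus common, 1.27 became −0.72 with the lowest 25% of sites left out and 0.12 with means. The cause was not tested. With libraries left out these ranged from −0.01 to 0.98 and from 0.26 to 2.27. The eTreg-specific minus cTreg-specific difference was negative in each of its alternatives, from −1.41 to −0.16 with libraries left out. Centring on the common-site median, like the block, leaves this difference at its main value by construction. Of 250 fold changes of named sites under alternatives, 38 moved by more than the spread between replicates, as did 3 of 76 list medians. The 250 include the block and the filter, neither of which can change the fold of a site. Core Treg, effector Treg and naive medians ranged from −2.24 to 0.43, −2.64 to 0.75 and −2.10 to 0.82 with libraries left out, and those of the other 4 lists likewise turned sign. The motif alternatives were not run. In R397W Foxp3 replicate 1, 1 read is a value of 2.63 at common sites and the median over sites with reads was 17 reads, so smaller steps in value are not resolved there.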

Other observations

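The tests of explanations in this part were chosen after the result was seen, except that of sites empty in a pair of libraries, while limma and DESeq2 were planned. The site with the lowest p in the comparison of genotypes lay inside Heg1 (chromosome 16, 33708064 to 33708464), with 731 ± 88.8 in WT and 209 ± 12.4 in R397W (SD, n = 2) and IgG between 44.5 and 258. The next was inside Chd7, a chromatin remodeller gene (chromosome 4, 8811025 to 8811425), with 420 ± 22.1 and 67.5 ± 38.1 and IgG between 63.2 and 245. An eTreg-specific site 16143 bp from Noxa1 (chromosome 2, 25111148 to 25111548) had 232 ± 17.3 and 29.4 ± 11.8. IgG near Noxa1 was also lower in R397W, at 59.5 and 48.5 against 150 and 74.0 in WT (replicates 1 and 2). It exceeded R397W Foxp3, at 37.7 and 21.1, in both replicates. Inside Cd247, the gene of the zeta chain of the T cell receptor complex (chromosome 1, 165837550 to 165837950), the values were 197 ± 56.1 and 19.9 ± 12.7, with IgG at most 56.2. A site 44 bp from Zfyve1 (chromosome 12, 83597089 to 83597489) went the other way, with 76.5 ± 10.1 in WT and 302 ± 37.4 in R397W. IgG near Zfyve1 was also higher in R397W, at 355 and 127 against 172 and 61.2 in WT (replicates 1 and 2). It exceeded Foxp3 in the replicates numbered 1 of both genotypes. All of these sites had adjusted p = 1 in limma. DESeq2 on recovered reads called Heg1, Chd7, Noxa1, Dusp1, Gtf2i and Mbnl1, with adjusted p-values of 0.000971, 0.0063, 0.0104, 0.00933, 0.0488 and 0.0488. At Dusp1 both R397W libraries were listed at 0, and at Mbnl1 (chromosome 3, 60472285 to 60472685, 74 bp from the gene) both WT libraries were. R397W Foxp3 at Mbnl1 was 14.7 and 149.9 and R397W IgG rose with it, at 9.92 and 84.7 (replicates 1 and 2). Near Gtf2i the value was 164 ± 24.3 in WT and 8.42 ± 4.49 in R397W, with IgG at most 17.2. A second site at Foxp3, 170 bp outside the gene (chromosome X, 7579306 to 7579706), had 64.3 and 15.8 in WT, 0 in both R397W libraries and at most 5.29 in IgG. It passed in neither limma (unadjusted p = 0.177) nor DESeq2. Over all 5521 sites, 661 were at 0 in both R397W Foxp3 libraries but not in both WT ones, and 88 the other way.

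The factors of the deposited signal were weighed first. A single spike-in factor per library shared by the 3 files is excluded, since the ratio of a pair of libraries' factors differed between files by up to 2.09-fold. Factors computed as medians of ratios over each file's own sites matched to within 6.87e-08 percent. A loss of Foxp3 signal at all sites of R397W cells would be removed by such factors and stays untested. Whether a spike-in step came before counting stays open too.

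The libraries numbered 2 had more sites without reads than those numbered 1 in all 4 groups. With both antibodies averaged per cell sample, 16.8% and 17.3% of sites lacked reads, at equal reads in the listed sites, in the samples numbered 1 and 57.5% and 59.2% in those numbered 2 (WT and R397W, exact permutation p = 0.33, two-sided, the smallest that 2 against 2 allows). Fewer reads in the listed sites is excluded as the whole cause, while library depth and duplicates are not known, because at 111274 reads in the listed sites of each library the lowest share without reads was 46.1% among libraries numbered 2 and the highest was 28.6% among those numbered 1. Few distinct fragments, with sites lost at random, is a candidate explanation and no biological one was tested, since sites empty in a pair of libraries numbered 2 were 1.07 times the number given by independent loss (median of 6 pairs). Among the 552 strongest sites by the libraries numbered 1, the libraries numbered 2 lacked reads at 4.53% (WT Foxp3), 10.7% (R397W Foxp3), 25.2% (WT IgG) and 15.6% (R397W IgG).

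The lower ratio of eTreg-specific to cTreg-specific reads in R397W was a log2 difference of −0.65 in Foxp3 libraries, where no library factor enters it, and −0.66 with each class capped at its 99th percentile, which argues against a few sites taking most of the reads. The IgG libraries of the same genotypes differed by −0.35 (pooled SD 0.11, bootstrap SE 0.11), with −0.50 and −0.19 for the replicates numbered 1 and 2, but with the cap by −0.29 (pooled SD 0.16), with −0.52 and −0.07, which is within 2 pooled SDs. In the share of sites with reads the IgG difference was −0.16 (pooled SD 0.03). IgG thus moved with Foxp3 in this share and in the uncapped reads, which a change of Foxp3 binding alone would not give. With 2 libraries per genotype and the capped reads within 2 pooled SDs, that explanation could not be decided. A change shared by both antibodies as the whole cause stays open too, as the Foxp3 minus IgG difference in reads was −0.30 (pooled SD 0.26, bootstrap SE 0.14). The values behind it were −0.06 and 0.46 in WT and −0.14 and −0.06 in R397W. The difference was −0.57 without WT replicate 1 and −0.04 without WT replicate 2. In the share of sites with reads it was −0.07 (pooled SD 0.03), from −0.10 to −0.04 with a cell sample left out in turn. A difference in cell makeup between the genotypes is untested. Relative to common sites, the IgG difference was 0.01 for eTreg-specific and 0.35 for cTreg-specific sites, and the Foxp3 minus IgG difference for eTreg-specific sites was −0.41 (pooled SD 0.10) in reads and −0.18 (pooled SD 0.23) in the share of sites with reads, so the reads argue against a shared change for that part and the share of sites leaves it open.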
